A study of Mus musculus with 18 samples.

How the data were processed

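The libraries came from mice carrying eGFP under the promoter of Pou4f3, a transcription factor of hair cells, the mechanosensory cells of the inner ear. Per the labels, sensory epithelia of the cochlea (hearing) and the utricle (balance) were dissected at embryonic day 16 (E16) and at postnatal days 0, 4 and 7 (P0, P4 and P7), dissociated with enzymes and sorted. Cells with the brightest GFP were collected as hair cells, and cells with the lowest fluorescence as surrounding cells. Polyadenylated RNA was amplified with the Ovation 3'-DGE system, which enriches the 3' ends of transcripts, and made into non-directional Illumina libraries. The labels name FastQC, DESeq and the mm9 genome build without versions, and they do not state the aligner or the tool that counted the reads.

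The deposited table holds 16 value columns for 20207 genes, of which 19693 (97.5%) are protein coding, while the labels list 18 samples. Hair cells at P0 have 2 samples per organ, sequenced in paired-end and single-end mode, but 1 column per organ, and how these were joined is not stated. The deposited values are a normalized signal: read counts per gene divided by 1 size factor per library, with no scaling to gene length or to the library total. This was read from the values, because in each of the 16 columns 100% of the nonzero values are whole multiples, within 0.01, of the smallest nonzero value. The unit therefore differed from the raw counts that the plan had assumed, and the test planned for normalized values was used. The edgeR test planned for counts was run beside it on the recovered reads. Reads per gene were recovered by dividing each value by the worth of 1 read. The deposited fold of GFP-positive over GFP-negative cells is a ratio, per the file headers, and equals the ratio of the mean values of 8 and 8 columns to within 1.83e-07. The deposited FDR column holds an adjusted p-value of the authors' comparison of GFP-positive with GFP-negative cells, and the method of adjustment is not stated. In the table, 529 genes have no read in any column and 21 symbols stand on more than 1 gene.

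Recovered depth ran from 2665393 to 51210752 reads per library. A count of 0 allows up to 3 reads, which corresponds to between 0.868 and 17.4 normalized counts depending on the library. Reads came through amplification without molecular identifiers, so intervals and floors cover counting error only. Across the 120 pairs of columns, correlations of log2 values over genes ran from 0.731 to 0.980, and no pair was identical.

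Genes with a value of at least 1 in at least 4 libraries were tested, which left 17796. Values were analysed as log2(value + 1) with limma-trend (limma 3.58.1 in R 4.3.3), with terms for cell type by organ and cell type by age, age being a factor of 4 levels. This model has 10 coefficients, which leaves 6 residual degrees of freedom, and limma added 6.32 prior degrees of freedom. Hair and surrounding cells share 1 residual variance per gene, so their spread was assumed equal. Each organ, cell type and age has 1 column, so libraries of the other organ and ages serve as replicates, and the residual holds the interaction of organ and age as well as library noise. Nothing in the labels says that libraries came from separate animals, so p-values measure only the spread between these libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 passed the test. Age trends are linear contrasts over the order E16, P0, P4, P7, given as log2 change per step. Differences between organs or cell types were tested as interaction terms, and the trend difference between organs in hair cells used a model with an added linear term for each organ, with 4 residual and 6.88 prior degrees of freedom.

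Gene lists were tested with camera (limma) at a preset correlation between genes of 0.01 and adjusted over the 19 lists within a comparison, with a correlation estimated from the data and with fry beside it. The lists covered hair cell transcription factors, stereocilia and mechanotransduction, the ribbon synapse, hair cell ion channels and calcium buffers, supporting cell markers, tectorial and otolithic membrane matrix, the Notch pathway, cochlear organ genes, vestibular organ genes, motile cilium genes, the cell cycle, hereditary deafness genes, and immediate early and heat shock genes. Further lists held markers of other cell types that the gate for surrounding cells could hold, namely mesenchyme, glia, neurons, blood and immune cells, endothelium, and melanocytes with ion-transporting epithelium. The deafness list shares 25 members with the stereocilia list, and the glia list shares 1 with the supporting cell markers and 1 with the immediate early genes. Groups, lists, the tests of the 8 comparisons, most alternatives and the rule for named genes were set before the data were examined, and those chosen later are named as such. That rule took, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among those that passed, had a mean of at least 10 in the higher group, changed the same way in every organ and age (for trends, P7 against E16 in both organs) and had no provisional symbol of the Gm or Rik kind. For the comparisons of differences, where the rule names no higher group, the mean was the highest of the groups compared. It added up to 4 members per list with the largest change among those that passed, or the 2 most abundant members where none passed, and 18 genes given in any case: Pou4f3, Atoh1, Gfi1, Myo7a, Espn, Otof, Tmc1, Tmc2, Slc26a5, Ocm, Ikzf2, Gata3, Spp1, Sox2, Jag1, Jag2, Dll1 and Mki67. Pou4f3 drives the GFP used for the sort, so its difference checks the labels and is no finding. Some genes that the rule names are left out of the text. Of the 288 genes named by the rule, 14 overlap another gene, which non-directional libraries cannot resolve. They are Col9a3, Syn1, Hbb-b1, Hbb-b2, Pmel, Sox2, Smoc2, Sox1, Kcnj13, Cacna2d4, Strc, Bmp4, Ccna2 and Pvt1.

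The test was also run on simulated counts with a dispersion of 0.1 and with 100 genes changed at each of 2 folds. Apart from these changes, every library had the same mean per gene, scaled to its depth, and the same dispersion. Other effects of age, organ or cell type, and unequal spread between libraries, were not simulated. The shares below hold for that setting only. At 8-fold it recovered 100 of 100 genes for hair against surrounding cells, for the organs within hair cells and for the age trend in hair cells, and 90 of 100 for the organ difference of the hair cell enrichment. At 2-fold it recovered 58, 15, 97 and 2 of 100 in these 4 comparisons, where the trend fold is per step. Unchanged genes made up 2.47% of the calls for hair against surrounding cells, 10.2% for the organs within hair cells, 16.2% for the trend in hair cells, 6.12% for the organ difference of the enrichment and 17.5% for the trend difference between organs. In these last 4 comparisons, 1, 5, 4 and 6 of the unchanged genes called had a mean of at least 50, of 13, 38, 6 and 28 called in all. These data vary more, with a common biological coefficient of variation of 0.506 in edgeR. With a dispersion of 0.26, near its square, 99, 89, 100 and 28 of 100 genes were recovered at 8-fold and 13, 0, 58 and 0 at 2-fold in the first 4 comparisons, and unchanged genes made up 0.885%, 11.0%, 8.14% and 3.45% of the calls. For the trend difference between organs these were 98 and 2 of 100, and 12.3%.

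Alternatives were pseudocounts of 0.5 and 5, no filter on low values, a filter at 5, recomputed median-ratio and upper-quartile factors, limma-voom and DESeq2 1.42.0 on the recovered reads, other models, and each library left out in turn. For differences between organs, the 16 fits with a library left out are not 16 separate checks. Leaving out either organ's library of an age and cell type gives the same estimate, because the age term fits the other exactly. For the organs within 1 cell type, leaving out a library of the other cell type does not change the estimate. It can still change the count, through the shared variance and its degrees of freedom. The alternatives chosen after seeing the data were TMM factors, the edgeR 4.0.16 quasi-likelihood test with TMM on the recovered reads, a filter at a mean of 50, the fits without the 4 P0 libraries or without 6 libraries rich in chemosensory receptor reads, and the share of those reads as a covariate. Without those 6 libraries, utricular hair cells are the P7 library alone. The model then fits the remaining hair cell libraries exactly, so its residual comes from surrounding cells only. Counts of passing genes from that fit are given only for comparisons within surrounding cells. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The comparison of replicate P0 hair cell libraries was left out, because the table holds 1 column for each of those groups.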

Results

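RNA was measured in 16 libraries of sorted mouse inner ear cells, covering hair cells and surrounding cells of the cochlea and the utricle at E16, P0, P4 and P7. Each combination of organ, cell type and age had 1 column of values, so there were 8 hair cell and 8 surrounding cell libraries, and values within 1 organ, cell type and age have no replicate. Cochlear hair cells had 21413836 reads at E16, 51210752 at P0, 17039047 at P4 and 19544493 at P7. Utricular hair cells had fewer reads, with 2665393, 9344669, 4910972 and 17025164 at these ages. Cochlear surrounding cells had 20692640, 6600187, 27413391 and 50556463 reads, and utricular surrounding cells had 43489790, 17303764, 5631320 and 16370712. The first principal component of the 2000 most variable genes held 45.9% of the variance, with all hair cell libraries on one side of 0 and all surrounding cell libraries on the other, and the next component held 23.1%. On this next component the P0 libraries lay at 34.9 (cochlear hair), 106 (utricular hair), 129 (cochlear surrounding) and 96.9 (utricular surrounding cells). E16 utricular hair cells lay at 26.7, and every other library was below 0.

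Reads from chemosensory receptor genes (olfactory and vomeronasal receptors, 1365 genes, used in the nose) differed between libraries. Per 1000000 reads, P0 utricular hair cells had 9679 (Wilson 95% interval 9617 to 9742), P0 cochlear hair cells 3792 (3775 to 3808) and E16 utricular hair cells 2344 (2287 to 2403). P4 utricular hair cells had 1053 (1025 to 1082), P0 cochlear surrounding cells 2707 (2668 to 2747) and P0 utricular surrounding cells 922 (908 to 937). The other 10 libraries had between 31.6 and 87.6.

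**Figure D1:**
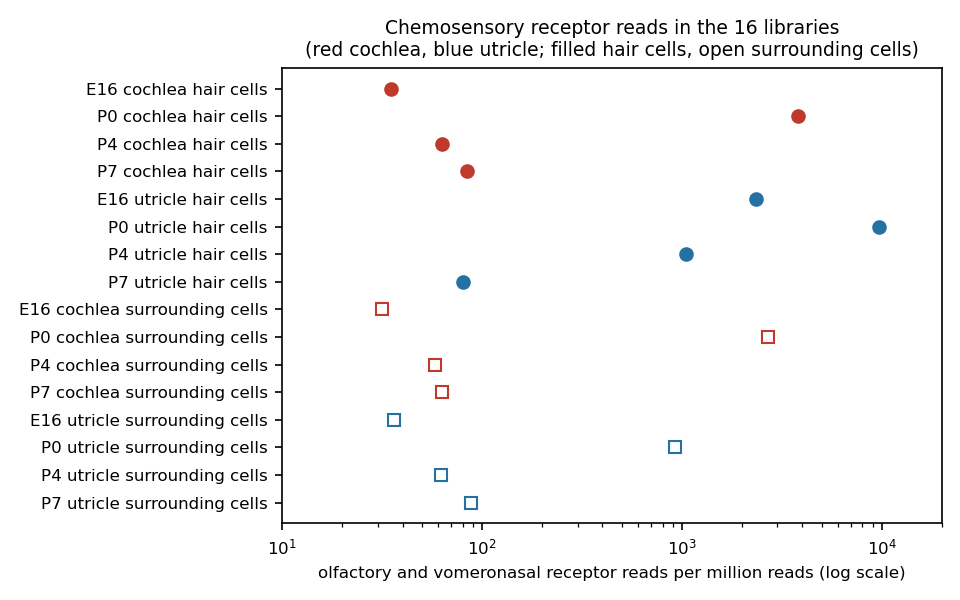
Chemosensory receptor reads per 1000000 reads (log axis) in each of the 16 libraries, 1 point per library. The 6 libraries named in the text lie between 922 and 9679, and the other 10 between 31.6 and 87.6.

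The comparison of hair cells with surrounding cells asked which genes mark hair cells across both organs and all 4 ages. Hair cells had more RNA of 35 of 37 genes that build and run the mechanosensory bundle, while all 14 mesenchyme genes were higher in surrounding cells. Smpx, an X-linked deafness gene (chromosome X, 154137050 to 154190521 in mm9, MGI:1913356), had a normalized count of 32670 ± 22150 in hair cells and 61.0 ± 79.6 in surrounding cells (mean ± SD, n = 8 each). Its log2 difference was 9.60 ± 0.33 (SE, adjusted p = 5.64e-09), higher in 8 of 8 pairs of organ and age. Col1a2, a chain of type I collagen (chromosome 6, 4455697 to 4491543, MGI:88468), had 348.5 ± 335.5 in hair cells and 36890 ± 22850 in surrounding cells. Its log2 difference was -7.11 ± 0.27 (adjusted p = 9.44e-09), lower in 8 of 8 pairs. In all, 3062 genes were higher and 3137 lower in hair cells, 6199 of the 17796 tested.

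Of 15 hair cell transcription factors, 12 were higher in hair cells and none lower (12 adjusted over the list alone), with a median log2 difference of 3.51 (camera adjusted p = 3.91e-09). They included Gfi1 at 9.37 ± 0.47, Lhx3 at 7.74 ± 0.45 and Atoh1, which starts hair cell formation, at 7.24 ± 0.52. Pou4f3 had 12.4 ± 7.71 normalized counts in hair cells and no read in any surrounding cell library. Against 3 reads per surrounding library, it was at least 3.65-fold higher, and the list median was 2.68 with Pou4f3 at that bound. Of 37 stereocilia and mechanotransduction genes, 35 were higher (35 higher and 1 lower adjusted over the list alone), with a median of 5.16 (camera adjusted p = 1.58e-21). Examples were Grxcr1 at 8.90 ± 0.42, the bundle phosphatase Ptprq at 8.16 ± 0.38, the channel subunit Tmc1 at 6.16 ± 0.35 and the unconventional myosin Myo7a at 5.11 ± 0.33. Of 17 ribbon synapse genes, 14 were higher (15 adjusted over the list alone; median 2.90, camera adjusted p = 1.84e-10). Nrxn3 had 7.07 ± 0.30 and Otof, a calcium sensor of vesicle release, 6.11 ± 0.35. Of 16 ion channels and calcium buffers, 14 were higher (14 adjusted over the list alone; median 3.62, camera adjusted p = 6.13e-09). Chrna9 at 7.56 ± 0.59 and Chrna10 at 7.02 ± 0.41, the subunits of the receptor for efferent nerve input, were among them. Prestin (Slc26a5), the motor protein of outer hair cells, was higher by 3.15 ± 0.92 (adjusted p = 0.0182), in 6 of 8 pairs.

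Among motile cilium genes, 25 of 30 were higher (28 adjusted over the list alone), with a median of 4.02 and a camera adjusted p of 3.35e-15. Spag6 at 6.93 ± 0.59, Armc4 at 6.46 ± 0.44 and Drc1 at 6.37 ± 0.44, all parts of the ciliary axoneme or its dynein docking, were examples. Of 77 deafness genes, 48 were higher and 8 lower (50 and 10 adjusted over the list alone; median 1.71, camera adjusted p = 3.84e-10, adjusted p = 0.052 with an estimated correlation). Of 16 cochlear organ genes, 9 were higher (9 adjusted over the list alone; median 1.57, camera adjusted p = 0.0014, adjusted p = 0.141 with an estimated correlation). Of 16 vestibular organ genes, 6 were higher and 3 lower (6 and 3 adjusted over the list alone; camera adjusted p = 0.0949). In the Notch pathway, 7 of 20 genes were higher and 5 lower (7 and 5 adjusted over the list alone; camera adjusted p = 0.445). The Notch ligands Dll1 at 5.12 ± 0.30, Dll4 at 4.62 ± 0.53 and Jag2 at 4.34 ± 0.53 were higher, and the target gene Hes1 was lower at -3.77 ± 0.47. The list's median was -0.01, its mean 0.75 and its test pointed up. The supporting cell markers Sox2, at 1.12 ± 0.28, and S100a1, at 4.11 ± 0.21, were higher in hair cells, while Id3 was lower at -3.55 ± 0.73. Of 19 supporting cell markers, 4 were higher and 9 lower (4 and 9 adjusted over the list alone; median -0.95, camera adjusted p = 0.0256, adjusted p = 0.257 with an estimated correlation).

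Markers of other cell types were tested as well. All 14 mesenchyme genes were lower in hair cells (14 adjusted over the list alone; median -4.98, camera adjusted p = 1.1e-13), among them Tbx18 at -7.13 ± 0.38 and Postn at -6.15 ± 0.49. Of 14 glia genes, 13 were lower (13 adjusted over the list alone; median -3.41, camera adjusted p = 3.91e-09, adjusted p = 0.052 with an estimated correlation). The myelin gene Pmp22 had -6.50 ± 0.48. Of 14 blood and immune genes, 12 were lower (13 adjusted over the list alone; median -3.67, camera adjusted p = 2.25e-07, adjusted p = 0.0846 with an estimated correlation). Of 10 endothelium genes, 6 were lower (7 adjusted over the list alone; median -2.50, camera adjusted p = 0.00152, adjusted p = 0.109 with an estimated correlation). Endomucin (Emcn) was one of them at -6.69 ± 0.31. Of 12 genes of melanocytes and ion-transporting epithelium, 6 were lower (7 adjusted over the list alone; camera adjusted p = 0.013, adjusted p = 0.0749 with an estimated correlation). Of 14 tectorial and otolithic matrix genes, 7 were lower and 2 higher (7 and 2 adjusted over the list alone; median -1.20, camera adjusted p = 0.00446, adjusted p = 0.13 with an estimated correlation). The collagen Col2a1 had -4.72 ± 0.30. Of 23 cell cycle genes, 18 were lower (19 adjusted over the list alone; median -1.81, camera adjusted p = 3.15e-08, adjusted p = 0.109 with an estimated correlation). Mki67, a marker of dividing cells, had -4.38 ± 0.50. Of 17 immediate early and heat shock genes, 13 were lower (13 lower and 1 higher adjusted over the list alone; median -2.37, camera adjusted p = 2.85e-08, adjusted p = 0.0846 with an estimated correlation). Ier3 had -5.42 ± 0.42. The neuron list was mixed, with 6 of 15 higher and 4 lower (6 and 4 adjusted over the list alone; camera adjusted p = 0.0949). The neurofilament genes Nefm at 6.30 ± 0.24 and Nefl at 6.20 ± 0.31 were higher in hair cells.

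Ikzf2 at 0.19 (adjusted p = 0.729), Gata3 at 1.30 (adjusted p = 0.0805), Spp1 at 1.10 (adjusted p = 0.569) and Jag1 at 0.15 (adjusted p = 0.782) did not pass. Of 575 tested receptor genes, 42 were higher and 1 lower in hair cells. The deposited analysis gave 978 genes with an adjusted p under 0.05, and each of these passed here in the same direction, beside 5221 others. Across the 8 comparisons, 71 of the list tests had a camera adjusted p under 0.05, and 7 of these held with an estimated correlation. The 7 were hair cell transcription factors (0.0182), stereocilia (0.0104), ribbon synapse (0.0104), channels and buffers (0.0297), motile cilium (0.0104) and mesenchyme (0.0104) in this comparison, and motile cilium between organs in hair cells (0.0285, but 0.0643 with the receptor share as a covariate). For hair against surrounding cells, 3850 genes passed with the receptor share as a covariate. Of 90 named genes that passed, 86 did so with each of the 16 libraries left out in turn; of the rest, Slc26a5 passed in 14, Pecam1 in 13, Tmc2 in 5 and Lmod3 in 4.

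**Figure D2:**
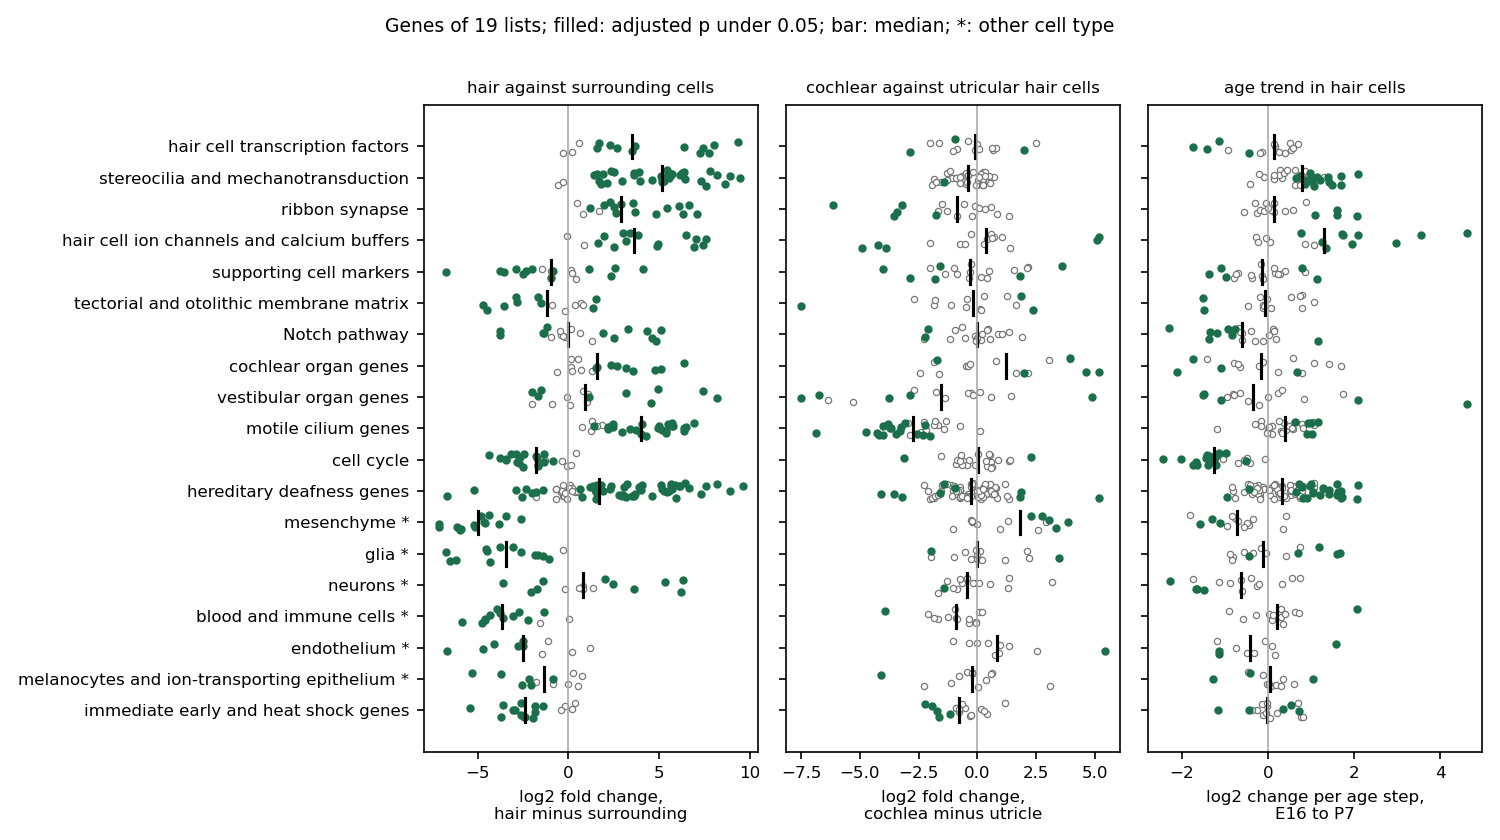
Log2 differences of the tested members of 19 gene lists for hair against surrounding cells, cochlea against utricle in hair cells, and the age trend in hair cells (log2 per step); filled points passed (adjusted p under 0.05), bars are list medians and stars mark other cell types. In the first panel the stereocilia median is 5.16 and the mesenchyme median -4.98; in the second the motile cilium median is -2.72.

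The comparison of cochlear with utricular hair cells asked how the hair cells for hearing and for balance differ. Utricular hair cells were richer in 17 of 30 motile cilium genes and in a synaptic glutamate transporter, while cochlear hair cells were richer in a calcium buffer, in the transcription factor Gata3 and in 5 of 14 mesenchyme genes. Otop1, needed for the calcium carbonate crystals of the utricle (chromosome 5, 38668643 to 38695456, MGI:2388363), had 21.7 ± 42.7 normalized counts in cochlear and 1030 ± 1109 in utricular hair cells (n = 4 each). Its log2 difference was -7.50 ± 0.69 (adjusted p = 0.00021), lower in the cochlea at 4 of 4 ages. Calb1, a calcium-binding protein (chromosome 4, 15808411 to 15833856, MGI:88248), had 28380 ± 23620 in cochlear and 459 ± 433 in utricular hair cells, a difference of 5.10 ± 0.84 (adjusted p = 0.00662) at 4 of 4 ages. Of the tested genes, 431 were higher and 691 lower in cochlear hair cells, 1122 in all.

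Of 30 motile cilium genes, 17 were lower in cochlear hair cells and none higher (25 lower adjusted over the list alone), with a median of -2.72 (camera adjusted p = 5.19e-14, adjusted p = 0.0285 with an estimated correlation). With the receptor share as a covariate, 4 were lower, with a median of -3.10 (camera adjusted p = 2.77e-14, adjusted p = 0.0643 with an estimated correlation). The axonemal dynein Dnah5 (chromosome 15, 28133521 to 28401800, MGI:107718) had 58.0 ± 76.2 normalized counts in cochlear and 4198 ± 2437 in utricular hair cells. Of 17 ribbon synapse genes, 5 were lower (6 lower and 1 higher adjusted over the list alone; median -0.87, camera adjusted p = 0.0323, adjusted p = 0.318 with an estimated correlation). They included Slc17a8, the transporter that loads vesicles with glutamate, at -3.55 ± 0.32 (adjusted p = 0.00021), Dnajc5b at -6.13 ± 0.70 and the calcium-binding protein Cabp1 at -3.43 ± 0.58. Of 16 vestibular organ genes, 4 were lower and 1 higher (6 and 1 adjusted over the list alone; median -1.56, camera adjusted p = 0.0323, adjusted p = 0.209 with an estimated correlation). The transcription factors Meis2 at -6.73 ± 0.89 and Sox2 at -2.88 ± 0.39 were lower, and Nr2f1 was higher at 4.88 ± 0.54. Other transcription factors lower in cochlear hair cells were Sox1 at -7.47 ± 0.71, Gbx2 at -6.89 ± 0.78 and Dlx2 at -6.55 ± 0.61. Of 16 cochlear organ genes, 4 were higher and 1 lower (6 and 3 adjusted over the list alone; median 1.21, camera adjusted p = 0.0502). Gata3 (chromosome 2, 9778705 to 9800227, MGI:95663) had 22540 ± 12310 in cochlear and 1416 ± 1661 in utricular hair cells, a difference of 4.64 ± 0.76 (adjusted p = 0.00655), which passed in 14 of the 16 fits with a library left out. Those 16 fits are not separate checks, since leaving out either organ's hair cell library of an age gives the same estimate. Slc26a5 was higher by 5.19 ± 1.30 (adjusted p = 0.0366) at 3 of 4 ages and passed in 2 of those 16 fits, and Ikzf2, at 1.98 ± 0.52 (adjusted p = 0.0444), in 4.

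Of 14 mesenchyme markers, 5 were higher in cochlear hair cells (7 adjusted over the list alone), with a median of 1.81 and a camera adjusted p of 9.06e-06 (adjusted p = 0.162 with an estimated correlation). Postn was higher by 3.85 ± 0.70 and Col1a2 by 2.76 ± 0.38. In the endothelium list, 1 of 10 was higher (1 adjusted over the list alone; median 0.83, camera adjusted p = 0.0323, adjusted p = 0.49 with an estimated correlation). This was Emcn at 5.43 ± 0.44. Of 17 immediate early and heat shock genes, 5 were lower (5 adjusted over the list alone; median -0.77, camera adjusted p = 0.0323, adjusted p = 0.757 with an estimated correlation). Fosb had -1.61 ± 0.26. The other 12 lists had camera adjusted p-values of 0.276 or more. Among these, stereocilia genes had 1 of 37 lower (0 adjusted over the list alone), ion channels and buffers 2 higher and 3 lower of 16 (3 and 4 adjusted over the list alone), supporting cell markers 2 and 4 of 19 (3 and 7 adjusted over the list alone) and deafness genes 3 and 6 of 77 (3 and 8 adjusted over the list alone). Median, mean and test differed in sign for channels (0.37, -0.07, up), glia (-0.01, 0.25, up) and the cell cycle (0.03, -0.02, up). For matrix genes (-0.17 and -0.59) and the Notch pathway (-0.03 and -0.16), the test pointed up. Spp1 at -6.36 (adjusted p = 0.0688), Otof at -1.68 (adjusted p = 0.0656) and Jag1 at 1.89 (adjusted p = 0.0504) did not pass. Of the 575 receptor genes, 1 was higher and 29 were lower.

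The median gene had a log2 difference of -0.22, which TMM factors moved by 0.245 to 0.02, and the share of passing genes that were higher in the cochlea moved from 38.4% to 59.7%. With TMM the list medians of hair cell transcription factors, matrix, Notch, deafness, glia and melanocyte genes, none with a camera call, turned from negative to positive. The count was 688 with edgeR, 2351 with DESeq2, 104 with hair cell libraries alone, 347 without the P0 libraries and 325 with the receptor share as a covariate. Without the 6 receptor-rich libraries the utricular hair cells are 1 library, P7, so that fit cannot test the organs and no count is given. Leaving out 1 hair cell library gave 574 without P0 cochlea, 583 without P0 utricle, 179 without P4 cochlea, 182 without P4 utricle, 1800 without P7 cochlea and 1822 without P7 utricle, and 26 of 60 named genes passed in each of the 16 fits with a library left out.

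Surrounding cells of the cochlea and the utricle were compared in the same way. Fewer genes passed, 11 higher and 10 lower in the cochlea, 21 in all. The transcription factor Foxf2 (chromosome 13, 31717685 to 31723275, MGI:1347479) had 748 ± 241 normalized counts in cochlear and 20.4 ± 17.3 in utricular surrounding cells (n = 4 each), a log2 difference of 5.61 ± 0.75 (adjusted p = 0.02) at 4 of 4 ages. Also higher were Crym, a thyroid hormone-binding protein, at 4.25 ± 0.60 and the matrix protein tenascin C (Tnc) at 3.87 ± 0.51. Lower in the cochlea were Sox1 at -5.37 ± 0.71, Otop1 at -5.11 ± 0.69, the connexin Gjb6 at -2.65 ± 0.34 and the melanocyte genes Tyrp1 at -4.66 ± 0.72 and Mlana at -5.15 ± 0.79.

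At the preset correlation 9 lists differed between the organs, and none of these calls held with an estimated correlation. Glia genes had a median of -1.38 (0 of 14 passing, 3 lower adjusted over the list alone; camera adjusted p = 1.44e-07, adjusted p = 0.161 with an estimated correlation). Blood and immune genes had -1.19 (0 of 14, 0 adjusted over the list alone; camera adjusted p = 6.94e-05, adjusted p = 0.357 with an estimated correlation). Melanocyte and ion transport genes had a median of -0.99 (1 of 12 lower, 2 adjusted over the list alone; camera adjusted p = 0.000784, adjusted p = 0.0733 with an estimated correlation). Neuron genes had 0.48 (1 of 15 higher, 2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0205, adjusted p = 0.357 with an estimated correlation). Vestibular organ genes had a median of -0.57 (1 of 16 lower, 4 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000946, adjusted p = 0.0733 with an estimated correlation). Cochlear organ genes had 0.39 (0 of 16, 3 higher adjusted over the list alone; camera adjusted p = 0.00792, adjusted p = 0.357 with an estimated correlation). The cell cycle list had -0.76 (0 of 23, 0 adjusted over the list alone; camera adjusted p = 0.000241, adjusted p = 0.357 with an estimated correlation). Supporting cell markers had -0.19 (1 of 19 lower, 5 adjusted over the list alone; camera adjusted p = 0.0127, adjusted p = 0.357 with an estimated correlation). Ribbon synapse genes had 0.15 (0 of 17, 2 higher adjusted over the list alone; camera adjusted p = 0.0439, adjusted p = 0.357 with an estimated correlation). The mean and median differed in sign for matrix genes (median 0.02, mean -0.63, test down) and motile cilium genes (0.00, -0.10, test down). Gata3, at 2.98, did not pass (adjusted p = 0.255). Genes lower in the cochlea in both cell types numbered 6, and genes higher in both 2. Opposite directions had 1 and 0. Both lists use 1 variance per gene, and hair cell libraries hold some RNA of surrounding cell markers. The lists are therefore not independent, and the counts are not set against a chance value.

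The count was 3 with edgeR, 83 with limma-voom, 242 with DESeq2, and 0 with limma-trend without the P0 libraries (902 at an unadjusted p under 0.05) or without the 6 receptor-rich libraries (1291). It was 62 without either E16 hair cell library, 8 without P4 cochlear and 9 without P4 utricular hair cells, 45 without either E16 surrounding cell library, and 0 without any 1 of the P0, P4 and P7 surrounding cell libraries of either organ, with 689 to 888 genes at an unadjusted p under 0.05, so none of the 19 named genes passed in each of the 16 fits.

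The age trend in hair cells asked how their RNA changed as they matured from E16 to P7. Of the listed genes, 16 of 37 for stereocilia and 10 of 16 for channels and calcium buffers rose, while 17 of 23 of the cell cycle and 7 of 20 of the Notch pathway fell; no list call of this trend held with an estimated correlation. Oncomodulin (Ocm), a calcium buffer (chromosome 5, 144780676 to 144811478, MGI:97401), went from 6.24 normalized counts at E16 through 217 and 50070 to 472600 at P7 in the cochlea, and from 11.6 through 5945 and 31030 to 33700 in the utricle. It rose by 4.62 ± 0.54 log2 per step (adjusted p = 0.000461), in 2 of 2 organs. Mki67 (chromosome 7, 142881471 to 142908062, MGI:106035) went from 644 at E16 to 0 at P7 in the cochlea and from 2396 to 6.63 in the utricle, a trend of -2.43 ± 0.32 (adjusted p = 0.000768). In all, 1322 genes rose and 1620 fell.

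**Figure D3:**
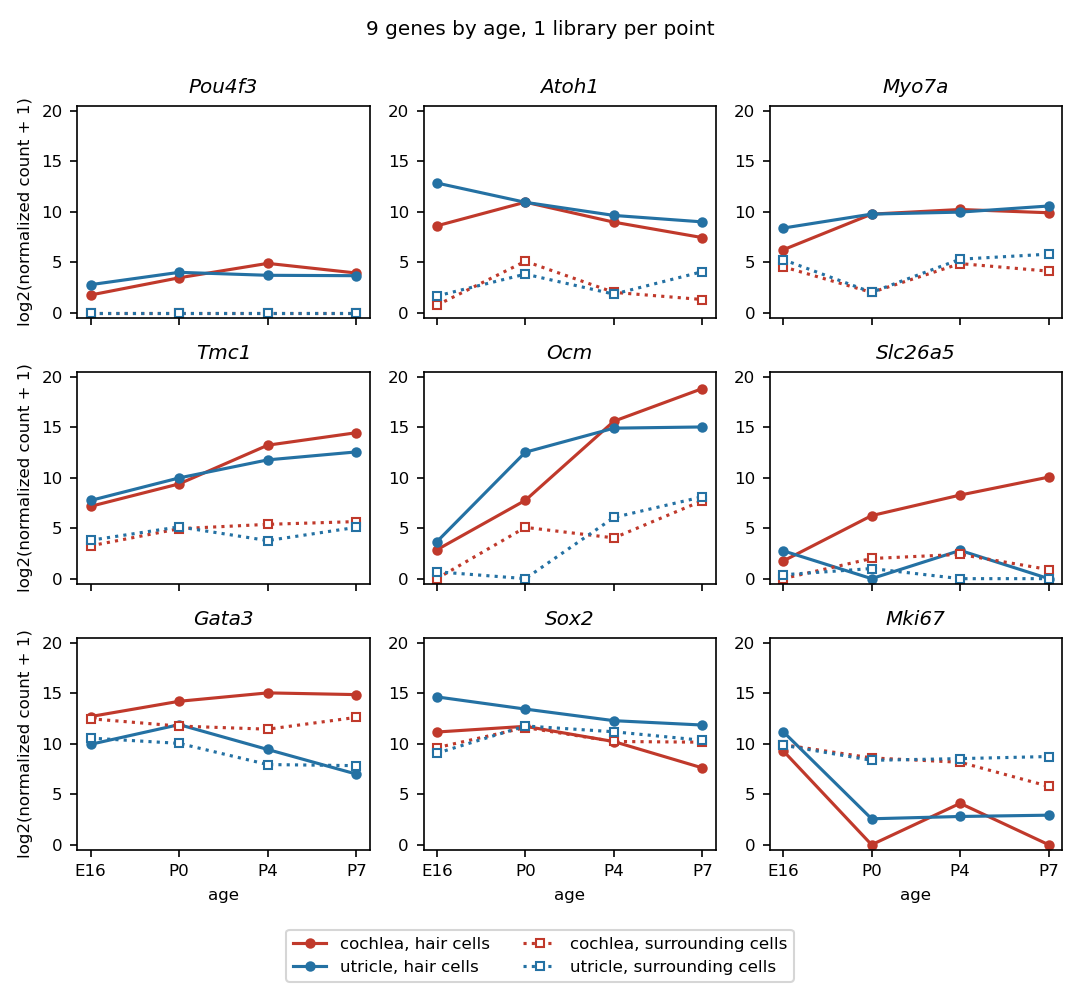
Log2(normalized count + 1) of 9 genes at E16, P0, P4 and P7; red is cochlea and blue utricle, filled circles with solid lines are hair cells, open squares with dotted lines are surrounding cells, and each point is 1 library. In cochlear hair cells Ocm goes from 6.24 to 472600 normalized counts.

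Of 37 stereocilia genes, 16 rose and none fell (21 rose adjusted over the list alone; median 0.79 per step, camera adjusted p = 5.51e-11, adjusted p = 0.095 with an estimated correlation). Tmc1 (chromosome 19, 20857948 to 21028692, MGI:2151016) rose by 2.10 ± 0.22 (adjusted p = 0.00035), from 143 to 22680 normalized counts in the cochlea and from 215 to 6061 in the utricle, and Espnl rose by 1.49 ± 0.28. Of 16 channels and calcium buffers, 10 rose (11 adjusted over the list alone; median 1.31, camera adjusted p = 1.43e-08, adjusted p = 0.095 with an estimated correlation). The calcium pump Atp2a3 rose by 3.55 ± 0.28 and the potassium channel Kcna10 by 2.96 ± 0.33. Of 17 ribbon synapse genes, 4 rose (4 adjusted over the list alone; median 0.14, camera adjusted p = 0.0144, adjusted p = 0.194 with an estimated correlation). They were Cabp2, Slc17a8, Otof and Rab3a, by 1.10 to 2.07. Of 77 deafness genes, 21 rose and 2 fell (24 and 3 adjusted over the list alone; median 0.34, camera adjusted p = 7.93e-07, adjusted p = 0.18 with an estimated correlation). Of 30 motile cilium genes, 6 rose (6 adjusted over the list alone; median 0.40, camera adjusted p = 0.000479, adjusted p = 0.18 with an estimated correlation). Outside the lists, the carbonic anhydrase Car12 rose by 2.74 ± 0.23 and the calcium channel subunit Cacna2d4 by 2.33 ± 0.30.

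Of 23 cell cycle genes, 17 fell (19 adjusted over the list alone; median -1.26, camera adjusted p = 1.28e-10, adjusted p = 0.18 with an estimated correlation). Cdk1 had a trend of -2.01 ± 0.38 and Ccna2 of -1.73 ± 0.27. Cep55, which acts in the last step of cell division, had a trend of -2.61 ± 0.26. Of 20 Notch genes, 7 fell and 1 rose (10 and 1 adjusted over the list alone; median -0.60, camera adjusted p = 0.0144, adjusted p = 0.283 with an estimated correlation). Hes1 had -1.37 ± 0.30 and Hes5 -1.35 ± 0.32. Mesenchyme genes had 3 of 14 falling (6 falling and 2 rising adjusted over the list alone; median -0.72, camera adjusted p = 0.0144, adjusted p = 0.283 with an estimated correlation). Vim had -1.57 ± 0.19. Neuron genes had 4 of 15 falling (7 adjusted over the list alone; median -0.61, camera adjusted p = 0.0188, adjusted p = 0.361 with an estimated correlation). Elavl4 had -1.66 ± 0.32. Glia genes had 4 of 14 rising and 1 falling (4 and 2 adjusted over the list alone; camera adjusted p = 0.477). Among transcription factors of hair cells, 4 of 15 fell (5 adjusted over the list alone; camera adjusted p = 0.842), with Isl1 at -1.13 ± 0.19, and Sox2 fell by 1.09 per step. Over these ages the mesenchyme median in hair cells went from 10.8% to 2.37% of the surrounding level in the cochlea and from 17.8% to 0.296% in the utricle, and that of glia from 28.4% to 10.6% and from 47.0% to 3.71%. A declining share of surrounding cell RNA was not separated from these falls, and 18 of 23 cell cycle genes and Hes1 were higher in surrounding cells. Median, mean and test differed in sign for transcription factors (0.14, -0.17, down), matrix (-0.05, 0.01, up), vestibular genes (-0.34, 0.13, down), glia (-0.10, 0.16, up) and immediate early genes (-0.01, 0.10, up), and supporting cell markers (-0.13 and -0.14) had a test pointing up. Atoh1 at -0.92 (adjusted p = 0.0749), Tmc2 at 0.86 (adjusted p = 0.0776) and Dll1 at -0.60 (adjusted p = 0.052) did not pass. Of the 575 receptor genes, 2 rose and 22 fell.

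The share of passing genes that rose was 44.9%, and 61.8% with TMM factors. The count was 1104 with hair cell libraries alone, 1564 with the receptor share as a covariate, 1821 without P7 cochlear and 1782 without P7 utricular hair cells, and 42 of 75 named genes passed in each of the 16 fits with a library left out.

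The same trend was tested in surrounding cells. Of the listed genes, 8 of 14 for glia, 5 of 14 for the matrix and 3 of 14 for blood and immune cells rose, and 2 of 23 of the cell cycle fell; no list call of this trend held with an estimated correlation. Otospiralin (Otos; chromosome 1, 94540795 to 94545418, MGI:2672814) rose by 3.22 ± 0.51 log2 per step (adjusted p = 0.00975), and the connexin Gjb6 (chromosome 14, 57742140 to 57744058, MGI:107588) by 1.60 ± 0.15 (adjusted p = 0.00114), each in 2 of 2 organs. The cartilage matrix gene Ucma rose by 2.56 ± 0.27. The embryonic globin Hbb-y had a trend of -2.79 ± 0.32 and the chromatin protein Hmga2 of -2.18 ± 0.24. In all, 252 genes rose and 120 fell.

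Of 14 glia genes, 8 rose (9 adjusted over the list alone; median 1.31, camera adjusted p = 1.09e-10, adjusted p = 0.106 with an estimated correlation). S100b rose by 2.02 ± 0.21, and the myelin gene Mbp by 1.85 ± 0.25. Of 14 matrix genes, 5 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.73, camera adjusted p = 6.61e-07, adjusted p = 0.106 with an estimated correlation). Tectb rose by 1.58 ± 0.29. Of 14 blood and immune genes, 3 rose (9 adjusted over the list alone; median 1.09, camera adjusted p = 2.7e-07, adjusted p = 0.129 with an estimated correlation). All 3 were C1q complement genes. Of 17 immediate early and heat shock genes, 5 rose (12 adjusted over the list alone; median 0.59, camera adjusted p = 5.4e-12, adjusted p = 0.106 with an estimated correlation). Zfp36 rose by 0.79 ± 0.14. Of 19 supporting cell markers, 4 rose (5 adjusted over the list alone; median 0.18, camera adjusted p = 0.00764, adjusted p = 0.38 with an estimated correlation). Of 23 cell cycle genes, 2 fell (14 adjusted over the list alone; median -0.80, camera adjusted p = 1.25e-13, adjusted p = 0.106 with an estimated correlation).

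Channels and buffers had 1 of 16 rising (6 adjusted over the list alone; median 0.74, camera adjusted p = 1.61e-05, adjusted p = 0.106 with an estimated correlation). This was Ocm at 2.53 ± 0.54. Ocm also rose in hair cells, and carryover of hair cell RNA into the surrounding cell libraries was not tested. Stereocilia genes had 2 of 37 rising (5 adjusted over the list alone; median 0.24, camera adjusted p = 0.00703, adjusted p = 0.38 with an estimated correlation). Deafness genes had 7 of 77 rising and 1 falling (13 and 2 adjusted over the list alone; median 0.14, camera adjusted p = 0.00375, adjusted p = 0.38 with an estimated correlation). Motile cilium genes (median -0.04, mean 0.06) and melanocyte genes (-0.04, -0.01) had tests pointing up. Genes rising in both cell types numbered 81, and genes falling in both 72. Rising in hair and falling in surrounding cells were 2, and the reverse 8. The lists share 1 variance per gene, and hair cell libraries hold some RNA of surrounding cell markers. These counts are therefore not set against a chance value. The share of passing genes that rose was 67.7%, and 54.1% with upper-quartile factors.

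The count was 987 with limma-voom, 1493 with DESeq2, 979 with surrounding cell libraries alone, 230 for P7 against E16, 1033 for any difference among ages, 180 without the P0 libraries, and 0 with limma-trend without the 6 receptor-rich libraries (3310 at an unadjusted p under 0.05). It was 749 without E16 cochlear and 759 without E16 utricular hair cells, 110, 147, 133 and 38 without cochlear surrounding cells of E16, P0, P4 and P7, and 18, 196, 147 and 26 without utricular ones, and 5 of 49 named genes (Gjb6, Hbb-y, Hmga2, S100b and Ucma) passed in each of the 16 fits.

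The organ difference of the hair cell enrichment asked for which genes the log2 difference of hair minus surrounding cells was higher in one organ. For genes lower in hair cells, a higher value can mean a smaller deficit there and not an enrichment. Rprm, which arrests the cell cycle, had 3045 ± 1040 normalized counts in cochlear hair cells and 112 ± 80.7 in cochlear surrounding cells, but 401 ± 211 and 488 ± 306 in the utricle (n = 4 each). The log2 difference of enrichment was 5.38 ± 0.64 (adjusted p = 0.00525), positive at 4 of 4 ages. The transcription factor Gbx2 (chromosome 1, 91824537 to 91827751, MGI:95668) had the opposite pattern, -8.46 ± 1.11 (adjusted p = 0.00685), with 510 ± 445 in utricular and 2.20 ± 2.13 in cochlear hair cells. Slc17a8 (chromosome 10, 89036765 to 89083998, MGI:3039629) had -3.59 ± 0.46, with 2153 ± 2700 in cochlear and 17680 ± 11760 in utricular hair cells, and Nefm had -3.73 ± 0.48. In all, 67 genes had a higher difference in the cochlea and 71 in the utricle, 138 together.

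Of 17 ribbon synapse genes, 3 had a higher difference in the utricle (5 adjusted over the list alone; median -1.63, camera adjusted p = 0.00114, adjusted p = 0.161 with an estimated correlation). Of 30 motile cilium genes, 1 did, Tekt2 (20 adjusted over the list alone; median -2.77, camera adjusted p = 1.02e-10, adjusted p = 0.0564 with an estimated correlation). In the mesenchyme list, 1 of 14 had a higher difference in the cochlea (Col1a2, 5 adjusted over the list alone; median 1.08, camera adjusted p = 9.03e-05, adjusted p = 0.161 with an estimated correlation). All 14 were lower in hair than in surrounding cells, so for Col1a2 this was a smaller deficit in the cochlea. In the glia list 1 of 14 had a higher difference in the cochlea (Fabp7, 4 adjusted over the list alone; median 1.32, camera adjusted p = 0.000539, adjusted p = 0.434 with an estimated correlation). The cell cycle list had a median of 0.63 (0 of 23, 2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0109, adjusted p = 0.809 with an estimated correlation). Matrix genes (median -0.06, mean 0.04) and cochlear organ genes (-0.05, 0.40) had tests pointing up. TMM factors moved the median gene by 0.228, and the share of passing genes higher in the cochlea from 48.6% to 67.2%.

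The count was 91 with no filter, 82 with edgeR, 304 with limma-voom, 1185 with DESeq2, and 0 with limma-trend without the P0 libraries (2337 at an unadjusted p under 0.05). It was 554, 17 and 274 without cochlear hair cells of E16, P4 and P7, 551, 19 and 274 without utricular ones, 73, 33, 21 and 18 without cochlear surrounding cells of E16, P0, P4 and P7 and 74, 32, 20 and 19 without utricular ones, and 7 of 30 named genes, Rprm, Gbx2, Slc17a8 and Nefm among them, passed in each of the 16 fits.

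The trend difference between cell types asked which genes changed with age in hair cells unlike in surrounding cells. Higher trends in hair cells were found for 2 of 16 channels and calcium buffers and 1 of 37 stereocilia genes, and lower ones for 3 of 14 glia and 3 of 17 immediate early genes. No list call held with an estimated correlation. Car12 differed by 2.73 ± 0.32 log2 per step (adjusted p = 0.0128), Atp2a3 by 2.46 ± 0.39, Tmc1 by 1.59 ± 0.31 and Otof by 1.53 ± 0.32, each in 2 of 2 organs. The fatty acid receptor Cd36 differed by -2.85 ± 0.37, Mbp by -1.89 ± 0.35 and Sox2 by -1.26 ± 0.25. In all, 77 genes had a higher and 152 a lower trend in hair cells, 229 together.

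Among stereocilia genes, 1 of 37 had a higher trend in hair cells (2 adjusted over the list alone; median 0.59, camera adjusted p = 3.04e-07, adjusted p = 0.144 with an estimated correlation). Channels and buffers had 2 of 16 higher (2 adjusted over the list alone; median 0.72, camera adjusted p = 0.000108, adjusted p = 0.144 with an estimated correlation). Motile cilium genes had 1 of 30 higher (1 adjusted over the list alone; median 0.31, camera adjusted p = 0.0011, adjusted p = 0.144 with an estimated correlation). In the ribbon synapse list 1 of 17 was higher (1 adjusted over the list alone; median 0.15, camera adjusted p = 0.00576, adjusted p = 0.144 with an estimated correlation). Deafness genes had 2 of 77 higher (2 adjusted over the list alone; median 0.22, camera adjusted p = 0.00186, adjusted p = 0.324 with an estimated correlation). Lower trends in hair cells were found for 3 of 14 glia genes (4 adjusted over the list alone; median -1.03, camera adjusted p = 2.4e-05, adjusted p = 0.144 with an estimated correlation). In the mesenchyme list 1 of 14 was lower (4 adjusted over the list alone; median -0.77, camera adjusted p = 0.000214, adjusted p = 0.144 with an estimated correlation). Immediate early genes had 3 of 17 lower (5 adjusted over the list alone; median -0.45, camera adjusted p = 0.000214, adjusted p = 0.311 with an estimated correlation). Matrix genes had 0 of 14 passing (5 lower adjusted over the list alone; median -0.63, camera adjusted p = 0.00105, adjusted p = 0.144 with an estimated correlation). Blood and immune genes had 0 of 14 passing (2 lower adjusted over the list alone; median -0.75, camera adjusted p = 0.00665, adjusted p = 0.324 with an estimated correlation). Supporting cell markers had 1 of 19 lower (3 adjusted over the list alone; median -0.67, camera adjusted p = 0.0193, adjusted p = 0.324 with an estimated correlation). The cell cycle list had 0 of 23 passing (0 adjusted over the list alone; median -0.34, camera adjusted p = 0.0299, adjusted p = 0.512 with an estimated correlation). Neuron genes had 0 of 15 passing (3 lower adjusted over the list alone; median -0.71, camera adjusted p = 0.0409, adjusted p = 0.324 with an estimated correlation). Signs differed for transcription factors (median 0.20, mean -0.05, test up), and cochlear organ genes (-0.11 and -0.05) had a test pointing up. The share of passing genes with a higher trend was 33.6%, 54.9% with TMM and 49.1% with upper-quartile factors.

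The count was 140 with TMM, 84 with edgeR and 1218 with DESeq2. It was 721, 121 and 71 without cochlear hair cells of E16, P4 and P7, 441 and 73 without utricular hair cells of E16 and P4, 20, 66, 51 and 27 without cochlear surrounding cells of E16, P0, P4 and P7, 66 and 38 without utricular ones of P0 and P4, and 0 without utricular ones of E16 or P7 (1719 and 1841 at an unadjusted p under 0.05), so none of the 30 named genes passed in each of the 16 fits.

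The trend difference between organs in hair cells asked which genes matured differently in cochlea and utricle. Gata3 differed by 1.87 ± 0.32 log2 per step (adjusted p = 0.0392), Ikzf2 by 1.40 ± 0.24 and Lmod3, which acts on actin filaments, by 4.78 ± 0.72, all higher in the cochlea. The calcium channel subunit Cacna2d1 differed by -2.47 ± 0.31 (adjusted p = 0.0218), the potassium channel Kcnj2 by -1.88 ± 0.30 and the growth cone protein Gap43 by -2.29 ± 0.41. In all, 43 genes were higher and 38 lower, 81 together. Of 16 cochlear organ genes, 3 were higher (8 higher and 1 lower adjusted over the list alone; median 1.31, camera adjusted p = 0.00105, adjusted p = 0.251 with an estimated correlation). Neuron genes had 2 of 15 lower (4 adjusted over the list alone; median -0.70, camera adjusted p = 0.00105, adjusted p = 0.347 with an estimated correlation). The cell cycle list had a median of -0.34 (0 of 23, 1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00452, adjusted p = 0.347 with an estimated correlation). Motile cilium genes had -0.31 (0 of 30, 0 adjusted over the list alone; camera adjusted p = 0.0475, adjusted p = 0.403 with an estimated correlation). Tests pointed down for ribbon synapse genes (median 0.17, mean 0.13), supporting cell markers (-0.16, 0.19), vestibular genes (0.11, -0.03), glia (0.03, 0.09), melanocytes (0.10, 0.15) and immediate early genes (0.04, 0.22).

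The count was 14 with no filter, 51 at a mean of at least 50, 4 with edgeR, 880 with DESeq2 and 0 with limma-trend and the receptor share as a covariate (1725 at an unadjusted p under 0.05). It was 502, 35 and 17 without cochlear hair cells of P0, P4 and P7, 505, 37 and 15 without utricular ones, and 5, 1, 1 and 1 without surrounding cells of E16, P0, P4 and P7 of either organ, and none of the 26 named genes passed in each of the 16 fits.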

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

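The tests of read depth, of the motile cilium genes, of the mesenchyme genes and of splits within ages given here were chosen after the results were seen; those of background reads and of few receptor genes in the receptor pattern, and the other splits of the libraries, were chosen before.

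Chemosensory receptor reads were high in 6 libraries, all 4 of P0 and the utricular hair cells of E16 and P4, which do not make up a group of the design. Low read depth as the whole cause was argued against, because P0 cochlear hair cells, the deepest of the 16 libraries, had 3792 receptor reads per 1000000. P4 utricular surrounding cells, with 5631320 reads in all, had 62.0. A part for low depth stays open and cannot be told apart, because 4 of the 6 were among the 6 shallowest of the 16 libraries, while the deepest of the 6 had 2.98 times the median depth. Background reads from genes the cells do not use may be the source, since 5 of the 6 were also among the 6 highest libraries for other tissue-restricted families (taste and trace amine receptors, defensins, keratin-associated proteins, prolactins), although these shares overlapped, at 40.4 to 93.6 per 1000000 reads in the 6 and up to 80.7 in the other 10. Expression of a few receptor genes stays open for part of the reads, because the 5 most read receptor genes held 65.6% of the receptor reads (median of the 6 libraries). That share ran from 56.1% to 90.6% in the 6 and from 38.8% to 58.45% in the other 10, so the ranges overlapped. Reads fell on 540 to 817 receptor genes in the 6 and on 85 to 470 in the other 10, which argues against a few genes as the whole cause. No other biological explanation was tested, since no group of the design matches these libraries.

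Of 30 motile cilium genes, 17 were higher in utricular than in cochlear hair cells. Background reads as the whole cause were argued against, because with the receptor share as a covariate the list median was -3.10 (SD 1.82, from -2.72 and 1.35) and its camera adjusted p was 2.77e-14, while genes passing went from 17 to 4 and the adjusted p with an estimated correlation from 0.0285 to 0.0643. The list and receptor medians were -2.73 and -2.77 at E16, -1.96 and -1.67 at P0, -2.95 and -1.99 at P4, and -3.48 and 0 at P7, so part of the difference before P7 stays open to background reads. Scaling was argued against, because the list median was -2.50 with TMM factors. A difference between the organs in motile cilium RNA stays open, and ciliated cells of another kind among the sorted cells were not tested.

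Of 14 mesenchyme genes, 5 were higher in cochlear than in utricular hair cells (adjusted p = 0.162 for the list with an estimated correlation), but at E16 the median over the list, as a percent of the surrounding level, was 10.8% in the cochlea and 17.8% in the utricle. Scaling was argued against by a median of 2.07 with TMM factors. Carryover of surrounding cells of every type alike stays open, because the organ difference of the enrichment, which allows for surrounding cells that differ between organs, had medians of 1.08 for mesenchyme, 1.32 for glia, 0.62 for endothelium and 0.32 for blood, and the first lay 0.755 above the last, less than the larger SD of 1.82. Carryover of mesenchymal cells alone cannot be told apart from expression in the hair cells, because 50% of the 10 abundant members lay within 2-fold of their median of 2.27% of the surrounding level in P7 cochlear hair cells, where a single source would give nearly all of them. The biological difference between the organs stays open and untested, and the list shares 1 gene with the deafness list.

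Other splits of the same libraries were compared with the real one. For hair against surrounding cells, 1 of 100 splits, the real one, called 6199 genes and the highest other 32, and for cochlea against utricle in hair cells 1 of 32 did, with 1122 against 311. For surrounding cells it was 1 of 32, with 21 against 3, and for the organ difference of the enrichment 1 of 100, with 138 against 44. Such splits mix ages, and a wrong split puts a real difference of organ or cell type into the residual. The low counts of the other splits therefore cannot exclude chance for these 4 comparisons. With labels swapped only within an age, 1 of 100 splits reached the real count for hair against surrounding cells (highest other 4854) and 2 of 100 for the organ difference of the enrichment (highest other 260). For the organs within hair or within surrounding cells only 8 such splits exist, too few for a share under 0.05, so chance was not excluded at fixed age there (highest other 90 and 3). For the trend difference between organs in hair cells, 3 of 32 splits gave at least as many genes, with 81 in the real split and 160 in the highest other, so chance was not excluded. Within ages it was 1 of 8, with 28 in the highest other, again too few splits.

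Named genes whose difference of hair minus surrounding cells differed between the organs by the interaction test (log2, cochlea minus utricle) were the following. For genes lower in hair cells, a positive value can mean a smaller deficit in the cochlea. Positive were Slc14a1 at 7.82, Mlana at 5.80, Gng8 at 5.74, Rprm at 5.38, Lgals1 at 5.30, Tmem176a at 5.09, Fabp7 at 3.93 and Col1a2 at 3.73. Negative were Gbx2 at -8.46, Dlx2 at -5.70, Dnajc5b at -5.44, Tnc at -4.86, Crym at -4.54, Tekt2 at -4.38, Nefm at -3.73, Slc17a8 at -3.59, Nrxn3 at -3.36 and Sox2 at -2.69. Of these genes, Rprm, Lgals1, Tmem176a, Gbx2, Nefm and Slc17a8 passed in each of the 16 fits with a library left out. Slc14a1 passed in 2 of them, Sox2 in 4 and the rest in 6 to 11.

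Named genes whose age trend differed between hair and surrounding cells (log2 per step, hair minus surrounding) were Calcb at 2.76, which had no read in P7 surrounding cells, Car12 at 2.73, Atp2a3 at 2.46, Emx2 at 2.18, Kcna10 at 2.17, Tmc1 at 1.59, Otof at 1.53 and Mlf1 at 1.11. Lower trends in hair cells were found for Cd36 at -2.85, Pou3f1 at -2.66, Prx at -2.58, Mbp at -1.89, S100b at -1.61, Vim at -1.58, Ier2 at -1.42, Sox2 at -1.26 and Dusp1 at -1.07. None of these passed in each of the 16 fits with a library left out, the range being from 2 fits (Kcna10) to 14 (Car12, Cd36, Pou3f1 and Prx).

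Named genes whose trend in hair cells differed between organs (log2 per step, cochlea minus utricle) were Lmod3 at 4.78, Dio2 at 3.52, Ghsr at 3.48, Lum at 1.90, Gata3 at 1.87 and Ikzf2 at 1.40. Lower in the cochlea were Rgs4 at -3.67, Trhde at -2.85, Cacna2d1 at -2.47, Gap43 at -2.29, Ntrk2 at -2.17 and Kcnj2 at -1.88. With a library left out, these genes passed in between 2 (Lmod3 and Lum) and 8 (Dio2) of the 16 fits.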

How the results depend on the processing

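The settings with TMM, edgeR, a mean of at least 50, the left-out P0 or receptor-rich libraries and the receptor covariate were chosen after the data were seen. No paired analysis was possible by replicate number, because each organ, cell type and age has 1 column, so the replicate block, the summed P0 libraries and the P0 comparison of cochlear with utricular hair cells were not run. Hair and surrounding libraries pair by organ and age, and with that block 4872 genes passed, 4788 of them among the 6199. Without the receptor-rich libraries, the trend difference between organs in hair cells was not tested. The number of passing genes stayed within 1.5 times with pseudocounts of 0.5 and 5, a filter at 5, and recomputed or upper-quartile factors in all 8 comparisons. Recomputed median-ratio factors gave the counts of the main test, because the deposited values already hold those factors, so that setting is no separate check.

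The cause of the following changes was not tested, except that left-out libraries leave fewer samples. For the organs within hair cells, the count of 1122 became 688 with edgeR, 2351 with DESeq2, 104 with hair cells alone, 347 without P0 and 325 with the covariate. Without the 6 receptor-rich libraries the utricular hair cells are the P7 library alone. That fit leaves no residual from hair cells, so counts that rest on hair cells are not given. For the organs within surrounding cells, 21 became 3 with edgeR, 83 with limma-voom, 242 with DESeq2, and 0 without P0 or without the 6 libraries. For hair against surrounding cells, 6199 became 2419 without the 6 libraries and 3850 with the covariate. The trend in hair cells, 2942, became 1104 with hair cells alone, 1014 without the 6 libraries and 1564 with the covariate. The trend in surrounding cells, 372, became 987 with limma-voom, 1493 with DESeq2, 979 with surrounding cells alone, 230 for P7 against E16, 1033 for any age difference, 180 without P0 and 0 without the 6 libraries. The organ difference of the enrichment, 138, became 91 with no filter, 82 with edgeR, 304 with limma-voom, 1185 with DESeq2, and 0 without P0. With the covariate 104 genes passed for it, 41 of them among the 138. The trend difference between cell types, 229, became 140 with TMM, 84 with edgeR and 1218 with DESeq2. With the covariate 218 genes passed for it, 125 of them among the 229. The trend difference between organs, 81, became 14 with no filter, 51 at a mean of at least 50, 4 with edgeR, 880 with DESeq2 and 0 with the covariate. The counts of 0 are from limma-trend. Without the 6 libraries, 1291 and 3310 genes had an unadjusted p under 0.05 for the organs and the trend within surrounding cells. Without P0 these were 902 within surrounding cells and 2337 for the organ difference, and with the covariate 1725 for the trend difference between organs. Of 71 camera calls, 7 held with an estimated correlation, and fry gave 43.

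With 1 library left out, counts ranged from 5104 to 7118 for hair against surrounding cells, 179 to 1822 and 0 to 62 for the organs within hair and surrounding cells, 1782 to 3443 and 18 to 759 for the trends in hair and surrounding cells, 17 to 554 for the organ difference of the enrichment, 0 to 721 for the trend difference between cell types and 1 to 505 for that between organs. The 5104 was without E16 cochlear surrounding cells, and the 7118 and the 3443 were without E16 cochlear hair cells. The libraries behind the other limits stand beside each comparison.

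Of 12354 values of named genes under 35 settings, 9842 kept their direction and side of the threshold, 2451 lost the call, 48 gained it and 13 turned direction, none of them a result that had passed. For hair against surrounding cells the 13 included Ikzf2 at -0.16 without the 6 libraries, -0.40 with the covariate and -0.21, -0.07 and -0.07 without P7 cochlear, E16 utricular and P0 utricular hair cells (range -0.21 to 0.58 over left-out libraries), Gata3 at -0.21 without the 6 libraries, and Spp1 at -0.67 without E16 cochlear hair cells (range -0.67 to 2.87). Jag1 had -0.35 with the covariate, -0.12 without P0 cochlear, -0.07 without P4 cochlear and -0.26 without E16 utricular hair cells (range -0.26 to 0.56). For the trend in hair cells, Spp1 had -0.37 without E16 utricular hair cells (range -0.37 to 3.88) and -0.36 without the 6 libraries. Among all genes that had passed, named or not, the sign turned without the 6 libraries for 40 (hair against surrounding cells), 25 (organs within hair cells), 39 (trend in hair cells) and 1 (trend in surrounding cells). It turned for 10 (hair against surrounding cells) with the covariate, and for 1 (trend in surrounding cells) each with P7 against E16 and without P0. In the fit without the 6 libraries, the utricular hair cells are the P7 library alone. The 25 turned signs between organs therefore rest on 1 utricular library, and the 39 of the trend on 1 cochlear library per age. Depth limits the utricular hair cells most, since 3 reads are worth 17.4 normalized counts in the E16 library of 2665393 reads.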

Other observations

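The gene families in this part, and their tests, were chosen after the data were seen. Of 42 collagen genes, 32 were lower and 1 higher in hair cells (median log2 difference -3.98, adjusted p = 0.0513 with an estimated correlation), and 6 of 42 rose with age in surrounding cells (median 0.39 per step, adjusted p = 0.144 with an estimated correlation). Integrins, the receptors for matrix proteins, had 18 of 30 lower and 1 higher (median -2.05, adjusted p = 0.0873 with an estimated correlation), and laminins of the basement membrane 6 of 11 lower (median -1.45, adjusted p = 0.0873 with an estimated correlation). Intraflagellar transport genes, which build cilia, had 9 of 14 higher in hair cells (median 1.35, adjusted p = 0.059 with an estimated correlation). Synaptotagmins, sensors and effectors of vesicle fusion, had 5 of 16 higher and 1 lower (adjusted p = 0.118 with an estimated correlation). Axonemal dynein heavy chains had 4 of 7 higher in hair cells (median 2.89, adjusted p = 0.0873 with an estimated correlation), and 4 of 7 lower in cochlear than in utricular hair cells (median -3.81, adjusted p = 0.0822 with an estimated correlation).

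Genes of respiratory complex I, the first enzyme of the mitochondrial electron chain, were higher in hair cells in 19 of 37 cases (median 0.65, adjusted p = 0.323 with an estimated correlation), and 22 of 37 rose with age in hair cells (median 0.63 per step, 0.75 with TMM factors, adjusted p = 0.244 with an estimated correlation). In surrounding cells none of them passed for the age trend with limma-trend (median 0.21), and none passed for the trend difference between cell types (median 0.40, adjusted p = 0.237 with an estimated correlation). Cytosolic ribosomal protein genes had 38 of 77 lower in hair than in surrounding cells (median -0.57, adjusted p = 0.343 with an estimated correlation) and 35 of 77 higher in cochlear than in utricular hair cells (median 1.01, 1.28 with TMM factors, adjusted p = 0.117 with an estimated correlation). Complex I genes had 11 of 37 higher in that comparison (median 0.84, adjusted p = 0.117 with an estimated correlation). Of the hair cell libraries, 3 of 4 utricular and 1 of 4 cochlear ones were rich in receptor reads. With the receptor share as a covariate, none of either family passed between the organs (medians 0.79 for ribosomal and 0.84 for complex I genes). With it, 8 ribosomal genes were lower and 4 complex I genes higher in hair cells, and 11 complex I genes rose. Replication helicase (MCM) genes had 4 of 6 lower in hair cells (median -1.56, adjusted p = 0.248 with an estimated correlation), and 5 of 6 fell with age in hair cells (median -1.14 per step, adjusted p = 0.244 with an estimated correlation).

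Genes that were higher in hair cells and rose with age in them numbered 674, and genes that were lower and fell numbered 704. Those higher and falling numbered 164, and those lower and rising 96. These counts share the hair cell libraries and 1 variance per gene, and a declining share of surrounding cell RNA in the hair cell libraries would give the same pattern, so they are not set against a chance value.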
